A study of Homo sapiens with 16 samples.

How the data were processed

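The series holds chromatin immunoprecipitation sequencing of human neural stem cells (NSC) with antibodies against H3K27ac, H3K4me1, SOX2 and YY1, and of human embryonic stem cells (ESC) with antibodies against SOX2 and YY1. Of 16 samples, 12 are immunoprecipitated libraries with a list of peaks, in 6 groups of 2, and 4 are input samples, which are not analysed here. Per the labels, libraries were sequenced as single-end reads of 50 bp. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.4.2, Picard, deepTools 3.4.3, MACS2 2.1.2 and bedtools 2.30.0 and the human genome build GRCh38 (hg38), without thresholds, control libraries or filters. Peak lists hold no read counts, so the depth of each library is unknown, and no interval that would need it is given.

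The deposited narrowPeak files hold 1 peak per line with the authors' fold enrichment at the summit over local background, which is a ratio. The deposited files also hold the −log10 p and −log10 q of each peak. The deposited score is 10 times the −log10 q as a whole number. No list held a peak with a q above 0.05. Fold enrichment was used to describe and rank regions, by the lower library of those compared, and for list members NSC-only and ESC-only regions were ranked together. Its levels were not tested between cell types. The authors also deposited 4 consensus region files for NSC, whose value is a ratio, the mean fold enrichment of the peaks of both libraries (equal within 0.0001 in all of their regions). NSC and ESC lists name chromosomes in different styles, which were brought to 1 style.

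Peaks on chromosomes 1 to 22 and X were used. Alternate and unplaced sequences were left out of the comparisons. Reproducible regions were made by merging the peaks of both libraries of a group and keeping merged regions with at least 1 peak from each. Made this way, 24430, 50147, 11557 and 6086 NSC regions compare with 24427, 50136, 11557 and 6086 deposited consensus regions for H3K27ac, H3K4me1, SOX2 and YY1, of which 24413, 50119, 11556 and 6084 had the same coordinates. Overlap means at least 1 bp. An NSC-only region overlapped no peak of either ESC library, an ESC-only region no peak of either NSC library, and a shared region was called in all 4 libraries. The summit of a region is that of its peak with the highest −log10 q.

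The gene table supplied (RefSeq genes on GRCh38) gives gene starts and ends without strand or transcription start sites. The plan had named transcription start sites, and both ends of each of 19974 protein-coding genes were used in their place. Proximal regions have their summit within 1 kb of either end, other regions are distal, and gene windows reach 50 kb from either end. No genome sequence was at hand, so the planned motif comparisons were not run. Of the 16 gene lists, 2 lost a member without a match in the table (TDGF1 from pluripotency and NDUFA4 from oxidative phosphorylation).

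Gene lists, groups, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names 15 genes in any case (among them SOX2, POU5F1, NANOG, LIN28A, SALL4, DPPA4, PAX6, NES, FABP7, OLIG2, HES5, NR2F1, POU3F2 and VIM). It adds up to 4 members of each list by the fold enrichment of a cell-type-specific and then a shared region, taking the lower library. It adds the gene nearest (within 100 kb) to the 10 NSC-only, 10 ESC-only and 5 shared regions of each factor with the highest fold enrichment, and to the 10 H3K27ac domains that cover most base pairs. Further members of the pluripotency, mesendoderm and HOX lists were named after their values were seen. Domains join H3K27ac regions up to 12.5 kb apart.

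Shares of peaks at gene ends were compared over libraries with two-sided exact permutation tests, which cannot give a p below 0.333 for 2 against 2 libraries. Their p-values measure the spread between libraries, and the labels do not say whether replicates come from separate cultures. Region sets were compared with two-sided Fisher's exact tests, given as odds ratios with 95% Woolf intervals, and shares with 95% Wilson intervals. Regions and genes are not independent replicates, so these tests compare sets and do not measure variation between cultures. Tests whose p was too small for the number format to hold are given by their intervals. Co-occupancy was set against 100 shuffles of region positions within chromosome extents (smallest p 0.0099). The 143 tests of gene lists were adjusted together by the method of Benjamini and Hochberg, and lists were compared with all other protein-coding genes.

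On simulated data (20 sets of 5000 regions with 30% shared) the procedure returned 30.1% ± 0.0353 (SD). Every simulated site was placed in both libraries of its cell type. This checks the counting of overlaps and not the effect of peaks missed in a library or of unequal depth. On simulated lists without an effect, 164 of 2880 Fisher's exact tests passed after adjustment. A test against 9999 random lists with the same runs of neighbouring genes (within 10 genes) and the same local gene density was added after the data were seen. It passed 1 of 2880 such tests, and it detected 9 of 40 planted lists where Fisher's exact test detected 37.

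The alternatives were stricter peaks (−log10 q of at least 5), equal numbers of peaks per SOX2 and YY1 library, a reciprocal overlap of 50%, the deposited consensus regions, gene ends within 2.5 kb, gene ends of long non-coding RNA genes added, summits inside H3K27ac regions, the nearest gene within 100 kb, lists against genes with a region, shuffles by distance to gene ends, pairing by replicate number, and leaving out each of the 12 libraries in turn, where the group then holds every peak of its other library. Equal numbers were those of the smallest library in each comparison, so the cut differed between results. An alternative without gene-rich intervals free of NSC peaks and the matched random lists were chosen after seeing the data. Chromosome Y, 1 locus and some genes that the rule names are not reported here.

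Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9, with seed 1 for every random draw.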

Results

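Chromatin immunoprecipitation followed by sequencing was carried out in human neural stem cells (NSC) and human embryonic stem cells (ESC). In NSC the targets were histone H3 acetylated at lysine 27 (H3K27ac, found at active promoters and enhancers), histone H3 monomethylated at lysine 4 (H3K4me1, found at enhancers), the HMG-box transcription factor SOX2 and the zinc-finger transcription factor YY1. In ESC the targets were SOX2 and YY1. Each of these 6 groups held 2 libraries, which gives 12 lists of called peaks. The peak lists carry no read counts, so the depth of every library is unknown. NSC H3K27ac had 40004 peaks in replicate 1 and 33593 in replicate 2. NSC H3K4me1 had 76897 and 99254 peaks, NSC SOX2 had 16218 and 17060, and NSC YY1 had 6613 and 19488. ESC SOX2 had 9931 and 8402 peaks, and ESC YY1 had 2242 and 4183.

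The first comparison asked how far the 2 libraries of each group named the same places. A reproducible region was defined as a stretch of merged peaks with at least 1 peak from each library. By this definition NSC held 24430 H3K27ac, 50147 H3K4me1, 11557 SOX2 and 6086 YY1 regions, and ESC held 6552 SOX2 and 2127 YY1 regions. SOX2 regions were narrow, with a median width of 370 bp in NSC and 278 bp in ESC, and YY1 regions had medians of 545 bp and 428 bp. H3K27ac and H3K4me1 regions had medians of 705 bp and 773 bp. The base pairs shared by both libraries, as a share of those covered by either (Jaccard index), came to 0.558 for H3K27ac, 0.395 for H3K4me1, 0.481 for NSC SOX2, 0.298 for NSC YY1, 0.502 for ESC SOX2 and 0.419 for ESC YY1. The YY1 libraries were unequal: 96.3% of the peaks of NSC YY1 replicate 1 overlapped a peak of replicate 2, against 31.5% in the other direction. In ESC the corresponding YY1 shares were 96.1% and 50.9%. With peaks held to a −log10 q of at least 5, NSC H3K4me1 regions numbered 24681, and with a reciprocal overlap of 50% they numbered 30814.

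YY1 peaks lay at gene ends and SOX2 peaks mostly did not. In NSC, 55.4% ± 10.4 (SD, n = 2 libraries) of YY1 peaks had their summit within 1 kb of either end of a protein-coding gene, against 10.6% ± 0.944 (SD, n = 2) of SOX2 peaks. In ESC the shares were 61.4% ± 9.30 for YY1 and 5.70% ± 0.579 for SOX2 (SD, n = 2 each). In NSC, H3K27ac peaks stood between YY1 and SOX2 at 36.6% ± 2.04, and H3K4me1 peaks stood below SOX2 at 7.23% ± 0.656 (SD, n = 2 each). Sequence within 1 kb of a gene end made up 2.4% of the chromosome lengths covered. In NSC the YY1 share exceeded the SOX2 share by 44.8 percentage points, and both YY1 libraries lay above both SOX2 libraries (two-sided exact permutation test, p = 0.333, the smallest that 2 against 2 libraries allow). SOX2 peaks lay at gene ends more often in NSC than in ESC, by 4.90 percentage points (exact permutation test, p = 0.333). The difference came to 2.02 percentage points when the SOX2 libraries of both cell types were held to the same number of peaks, 8402. For YY1 the NSC mean minus the ESC mean was −5.98 percentage points (exact permutation test, p = 0.667), which is within the spread of the libraries. It turned to 12.7 with equal numbers of peaks, to 1.40 without NSC YY1 replicate 2 and to 0.603 without ESC YY1 replicate 1.

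**Figure D1:**
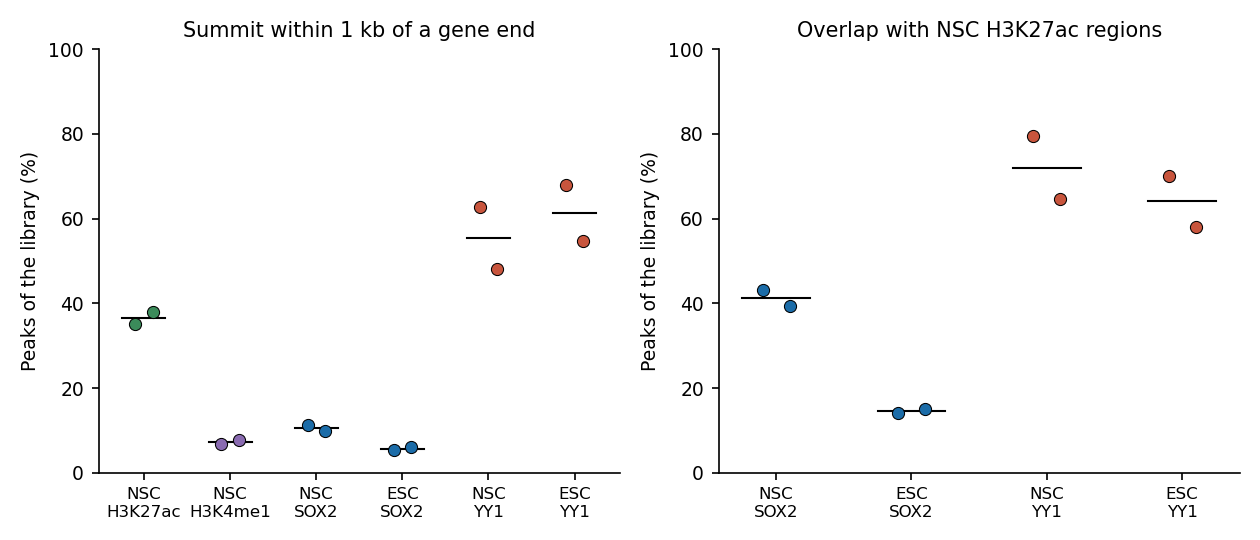
The left panel plots, for each library (points), the percentage of its peaks whose summit lies within 1 kb of a protein-coding gene end, and the right panel the percentage overlapping reproducible NSC H3K27ac regions; lines are means of 2 libraries. YY1 libraries lie between 48.0% and 68.0% in the left panel, and SOX2 libraries between 5.29% and 11.3%.

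The next comparison set the histone marks of NSC against the sites bound by each factor there. Most YY1 regions lay on H3K27ac, 4981 of 6086 or 81.8%, while SOX2 regions were split, with 5386 of 11557 or 46.6% on H3K27ac. H3K4me1 had the opposite order, at 16.0% of YY1 regions and 62.7% of SOX2 regions. By combination, 70.5% of YY1 regions carried H3K27ac alone, 11.4% both marks, 4.63% H3K4me1 alone and 13.5% neither. SOX2 regions divided into 29.7% with both marks, 16.9% with H3K27ac alone, 33.0% with H3K4me1 alone and 20.4% with neither. The odds of H3K27ac at YY1 over SOX2 regions were 5.16 (95% interval 4.79 to 5.57, Fisher's exact test on regions), and those of H3K4me1 were 0.113 (0.105 to 0.122). The H3K27ac difference was present within 1 kb of gene ends (91.0% against 82.6%, odds ratio 2.12, p = 7.18e-13) and away from them (66.2% against 43.2%, odds ratio 2.57, p = 1.18e-87, Fisher's exact test). Over libraries, 72.0% ± 10.6 of YY1 peaks and 41.2% ± 2.76 of SOX2 peaks overlapped H3K27ac regions (SD, n = 2 each). Without NSC YY1 replicate 1 the odds ratio came to 2.09 for all regions, 1.23 away from gene ends and 0.964 at gene ends. The YY1 set then held all 19488 peaks of replicate 2, without the need for a second call. Whether the missing library or the missing second call removed the difference at gene ends was not tested. With NSC SOX2 replicate 1 left out, the odds ratio away from gene ends was 3.63; with NSC H3K27ac replicate 2 left out, that at gene ends was 3.36.

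Most ESC SOX2 sites were not called in NSC, and most ESC YY1 sites were. Of the ESC SOX2 regions, 1670 of 6552 or 25.5% (95% Wilson interval 24.4 to 26.6) were called in both NSC libraries, against 1783 of 2127 or 83.8% (82.2 to 85.3) of the ESC YY1 regions. The odds ratio was 15.2 (13.3 to 17.2, Fisher's exact test on regions). For SOX2, 9062 regions were found in NSC with no peak in either ESC library (NSC-only), 4404 in ESC with no peak in either NSC library (ESC-only), and 1672 NSC regions were called in both libraries of both cell types (shared). For YY1 these counts were 3316, 242 and 1769. Position differed by factor, with 69.7% of ESC YY1 and 5.36% of ESC SOX2 regions proximal. ESC-only were 51 of 1482 proximal YY1 and 137 of 351 proximal SOX2 regions. Of the 242 ESC-only YY1 regions 191 were distal, as were 4267 of the 4404 for SOX2. The odds ratio was not split by position. Seen from NSC, 54.5% of YY1 regions were NSC-only and 29.1% shared, against 78.4% and 14.5% of SOX2 regions. Over pairs of 1 ESC and 1 NSC library, 25.2% to 27.7% of ESC SOX2 peaks and 66.8% to 87.1% of ESC YY1 peaks were called in NSC, so the ranges over library pairs did not meet. In the other direction, 13.6% to 15.4% of NSC SOX2 peaks and 9.81% to 42.6% of NSC YY1 peaks were called in ESC, and these ranges overlapped. Without ESC YY1 replicate 1 the odds ratio fell to 5.83, with a reciprocal overlap of 50% it was 4.89, and with equal numbers of peaks it was 24.5. Here equal numbers meant 2242 peaks in every SOX2 and YY1 library, and 12.6% of ESC SOX2 regions were then called in NSC. The share of ESC YY1 regions was 53.7% with a reciprocal overlap of 50%, and 66.6% to 88.5% over left-out libraries. A region without a call is not shown to be unbound, since calling depends on a depth that is unknown here.

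The SOX2 regions with the highest fold enrichment over background (the lower of the 2 libraries) included genes of several kinds. NSC-only regions stood in ITGA2, an integrin subunit, at 46.8-fold (GRCh38 chromosome 5, 52997118 to 52997853), in USP28, a deubiquitinase, at 42.3-fold, in the lens filament gene BFSP1 at 41.8-fold and in DICER1, the RNase of microRNA maturation, at 40.5-fold. The other 6 of the 10 highest were nearest to ARGLU1, B3GLCT, NAV2, PDHA2, VWA8 and REEP1, at 34.4- to 36.7-fold. ESC-only regions stood in NTN1, the axon guidance cue netrin 1, at 42.3-fold (chromosome 17, 9054669 to 9055139) and in NLGN1, a synaptic adhesion molecule, at 39.4-fold (chromosome 3, 174232286 to 174233010). Others among the 10 highest were nearest to STXBP5, LOC124901803, PJA1, SMAD7, CERS6, ITPRID1 and KDM4A, at 31.4- to 35.6-fold. Shared SOX2 regions were highest in the Wnt receptor gene FZD3, where the lowest of the 4 libraries was 33.8-fold, followed by SARS1, OTULIN, THBS3 and PCDH1.

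Of the YY1 regions with the highest fold enrichment, 5 of 5 shared, 6 of 10 NSC-only and 5 of 10 ESC-only ones lay within 1 kb of a gene end. The genes named are the nearest, and the farthest was MMUT, 87843 bp from its region. Shared regions were highest at C1orf174 (chromosome 1, 3899964 to 3901541), where the lowest of the 4 libraries was 37.0-fold, followed by LEMD2, the Mediator subunit gene MED25, ZFP37 and SLX4IP, and all 5 lay within 1 kb of a gene end. NSC-only YY1 regions were highest in WIZ, a zinc-finger gene, at 29.5-fold (chromosome 19, 15432564 to 15433010), followed by IPO5, ANKRD37, ECHS1, the neural factor gene SOX1 at 27.5-fold, BCL7A, the RNA-editing enzyme gene ADAR, HNRNPR, CCDC150 and MTMR8. ESC-only YY1 regions were highest in YWHAE, which encodes a 14-3-3 protein, at 30.5-fold (chromosome 17, 1399361 to 1400443), followed by RXRB at 14.9-fold, NAPEPLD, PPP1R10, DDX39B, MMUT, MOG, NLGN1, the histone methyltransferase gene NSD1 and DAXX at 11.2-fold. The ESC-only YY1 region at NLGN1 overlapped the ESC-only SOX2 region named there. RXRB, PPP1R10, DDX39B, MOG and DAXX lie in a stretch of chromosome 6 that has no peak in any of the 8 NSC libraries, which spans 5.00 Mb (28506997 to 33505663) and holds the major histocompatibility complex. It held 20 ESC YY1 regions and 21 ESC SOX2 regions. There were 60 gene-rich intervals of this kind (over 200 kb with at least 10 protein-coding genes), chosen after the data were seen, and they held 45 of the 242 ESC-only YY1 regions, or 18.6% (Wilson interval 14.2 to 24.0), and 120 of the 4404 ESC-only SOX2 regions. Of all ESC YY1 regions 2.12% lay in these intervals, which make up 4.71% of the sequence. Some of the intervals are long and nearly empty. The first 22.2 Mb of chromosome 15 held 27 protein-coding genes and 1 merged ESC peak. The share of the sequence is therefore no measure of how many YY1 regions to expect there.

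**Figure D2:**
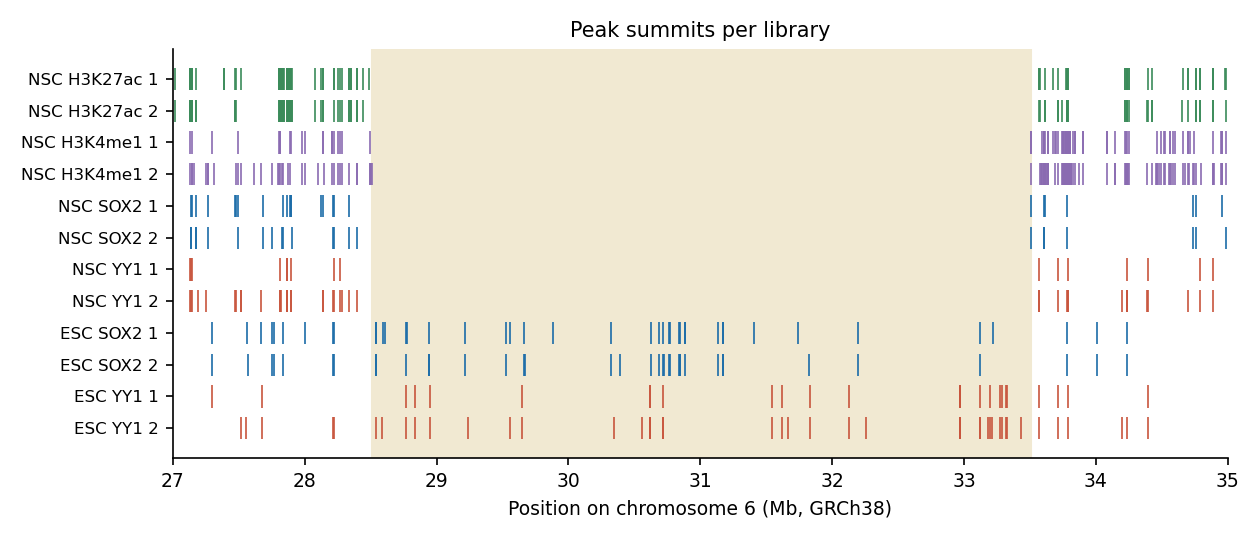
Each tick is a peak summit in 1 library, with its position on chromosome 6 in Mb from 27 to 35 on the x axis and the 12 libraries as lines of ticks; the shaded interval (28506997 to 33505663) has no peak in any NSC library. ESC SOX2 and ESC YY1 libraries have peaks across it, with 20 reproducible YY1 and 21 reproducible SOX2 regions.

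The SOX2 sites that differed between the cell types differed in NSC histone marks. H3K27ac was present in NSC at 43.9% of NSC-only SOX2 regions, at 55.7% of shared regions and at 105 of 4404, or 2.38%, of ESC-only regions. H3K4me1 was present at 63.3%, 62.4% and 14.4%. The odds of H3K27ac at NSC-only over ESC-only SOX2 regions were 32.0 (26.3 to 39.0), and those of H3K4me1 were 10.3 (9.33 to 11.3, Fisher's exact test on regions). Away from gene ends the H3K27ac shares were 40.8% and 2.02%, and at gene ends they were 81.6% and 13.9%. For YY1, H3K27ac lay at 78.4% of NSC-only regions, 88.1% of shared regions and 1 of 242 ESC-only regions (odds ratio 874, 122 to 6238), of which 45 lie in intervals without any NSC peak. This odds ratio was 129.7 without NSC YY1 replicate 2, 398 without NSC YY1 replicate 1 or without ESC YY1 replicate 1, 75.4 with equal numbers of peaks and 9.13 with a reciprocal overlap of 50%. H3K4me1 lay at 24.2% of NSC-only YY1 regions, 5.31% of shared regions and 3.31% of ESC-only regions. Of the 10 NSC-only SOX2 regions with the highest fold enrichment, 8 carried H3K27ac, as did 0 of the 10 ESC-only and 5 of the 5 shared regions. The SOX2 odds ratio was 17.7 without NSC SOX2 replicate 1, 15.2 with a reciprocal overlap of 50% and 18.6 when the SOX2 summit had to lie inside the H3K27ac region. Histone marks were not measured in ESC.

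**Figure D3:**
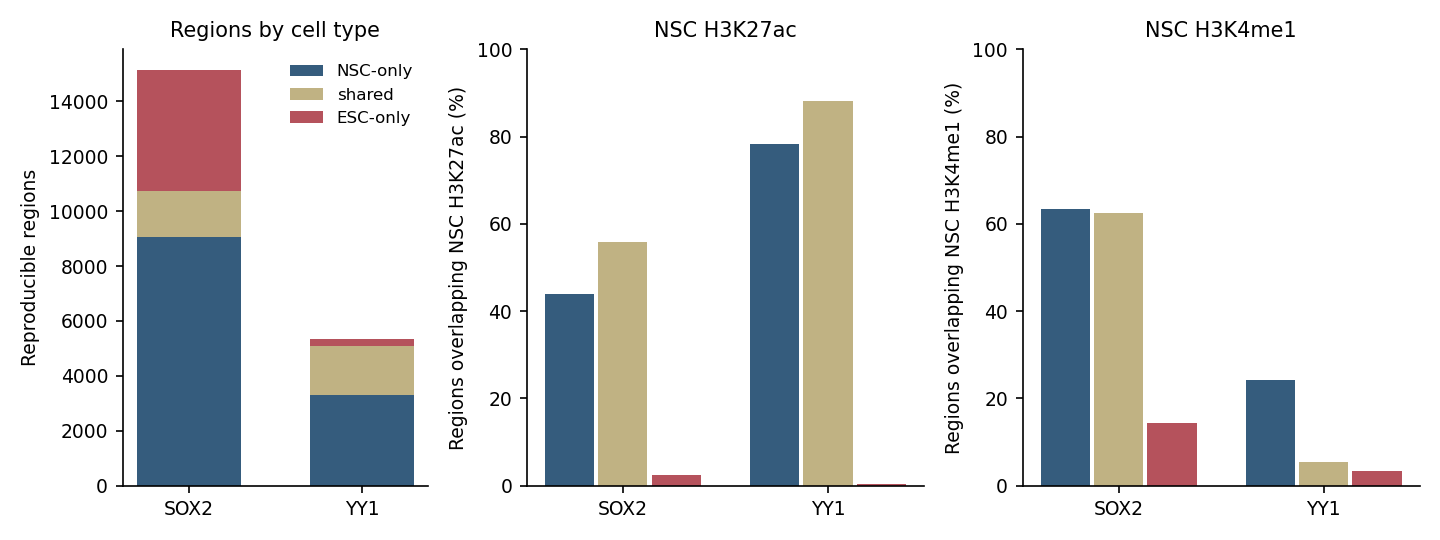
Bars give the number of reproducible regions found in NSC only, in both cell types (shared) or in ESC only for SOX2 and YY1 (left), and the percentage of each class overlapping reproducible NSC H3K27ac (middle) and H3K4me1 regions (right). H3K27ac lies at 43.9% of NSC-only and 2.38% of ESC-only SOX2 regions.

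Genes of the stem cell states illustrated these classes. Around SOX2 itself, NSC held 12 SOX2 regions and 13 H3K27ac regions within 50 kb, and ESC held 5 SOX2 regions. The strongest was the same site in both cell types (chromosome 3, 181715928 to 181716414 in NSC), with a fold enrichment of 21.9 ± 1.82 in NSC and 24.3 ± 4.22 in ESC (SD, n = 2 each). POU5F1, which encodes the pluripotency factor OCT4, had 3 ESC SOX2 regions (strongest 17.3 ± 1.68, SD, n = 2, chromosome 6, 31172897 to 31173259) and no region of any NSC target, and it lies in the chromosome 6 stretch without NSC peaks. NANOG, a homeobox factor of pluripotency, had 4 ESC SOX2 regions (strongest 13.4 ± 0.0766, SD, n = 2) and no reproducible NSC region. LIN28A, an RNA-binding protein gene, had 4 SOX2 regions in each cell type, the zinc-finger gene SALL4 had 1 in each, and DPPA4 had 3 in NSC and 2 in ESC. NSC SOX2 regions without an ESC SOX2 region nearby were found at FABP7, a radial glial fatty acid binding protein (4 regions, strongest 11.9 ± 1.11), at the orphan nuclear receptor NR2F1 (6 regions, 13.3 ± 1.11), at the POU factor POU3F2 (5 regions, 12.45 ± 5.09) and at PAX6, a regulator of neural progenitors (2 regions, 6.27 ± 0.850; SD, n = 2 for each). Within 50 kb, FABP7, NR2F1 and PAX6 each had 1 ESC SOX2 peak in 1 library alone. At NES, which encodes the intermediate filament nestin, the strongest SOX2 site was common to both cell types, at 23.5 ± 1.53 in NSC and 19.4 ± 3.77 in ESC (SD, n = 2 each). VIM had 2 SOX2 regions in NSC and 1 in ESC. No reproducible SOX2 region was called within 50 kb of OLIG2 or HES5 in either cell type, and HES5 had 1 ESC SOX2 peak in replicate 2 alone. OLIG2 had 2 NSC H3K4me1 regions and HES5 had 1 ESC YY1 region.

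Gene lists fixed from textbook roles were then compared between genes with an NSC-only and no ESC-only SOX2 region within 50 kb (NSC-specific) and genes with an ESC-only and no NSC-only region (ESC-specific). Regions called in both cell types, in full or in part, did not enter, so an NSC-specific gene such as DPPA4 or VIM can also hold ESC SOX2 regions. Among other genes 4865 were NSC-specific and 2267 ESC-specific. Pluripotency genes ran against this, with 2 NSC-specific and 12 ESC-specific members of 35 (odds ratio 0.0777, 0.0174 to 0.347, adjusted p = 0.000208 by Fisher's exact test). Among the 12 were POU5F1, NANOG, DPPA5, ZFP42, KLF5, FOXD3, L1TD1, FOXH1, the telomere protein gene TERF1 (27.5-fold) and LEFTY1 and LEFTY2, antagonists of Nodal signalling that share 1 region at 28.5-fold (chromosome 1, 225899305 to 225899694). The 2 NSC-specific members were LIN28B and DPPA4, and 11 members had regions of both kinds. Genes of mesendoderm and other germ layers had 3 NSC-specific and 8 ESC-specific members of 28 (odds ratio 0.175, 0.0464 to 0.661, adjusted exact p = 0.0175). Among the 8 were the T-box genes TBXT and EOMES, GSC (13.9-fold), FOXA2 (11.5-fold), CER1, CDX2 (14.6-fold) and TFAP2A. HOX genes had 0 NSC-specific and 11 ESC-specific members of 39 (odds ratio 0.0203, adjusted exact p = 1.95e-05), which were HOXB1 to HOXB4, HOXB13 and HOXD8 to HOXD13 and rested on 5 distinct regions. Against random lists with the same runs of neighbouring genes and the same gene density, the adjusted p was 0.00376 for pluripotency, 0.0366 for mesendoderm and 0.0372 for HOX genes. The mesendoderm call was lost with stricter peaks (adjusted exact p = 0.235) and with equal numbers of peaks (adjusted exact p = 0.298), and the HOX call was lost when each region went to its nearest gene (adjusted exact p = 0.190). Over left-out SOX2 libraries the odds ratio ran from 0.0496 to 0.125 for pluripotency, from 0.106 to 0.276 for mesendoderm and from 0.0120 to 0.0256 for HOX genes, and with a reciprocal overlap of 50% that of pluripotency was 0.0369.

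The other 13 lists did not pass the test of a difference between NSC-specific and ESC-specific SOX2 genes. Neural stem and progenitor genes had 28 NSC-specific and 7 ESC-specific members of 53, with 10 of both kinds (odds ratio 1.88, 0.819 to 4.31, adjusted exact p = 0.268). The highest were MSI1, an RNA-binding protein of neural progenitors, at 21.9-fold, VIM at 20.2-fold and ZIC1 at 18.4-fold, all NSC-specific, and the homeobox gene MEIS2, of both kinds, at 20-fold. Notch, Wnt, Hedgehog and FGF signalling genes had 26 NSC-specific, 10 ESC-specific and 12 members of both kinds, among them TCF7L1 (19.3-fold, ESC-only), ETV1 (18.9-fold, NSC-only), SPRY1 (17.4-fold, ESC-only) and JAG1 (17.0-fold, NSC-only). Neuronal differentiation genes had 11 and 7 (GAD2 at 16.8-fold in ESC), glial genes 6 and 6 (NKX2-2 at 13.7-fold in NSC), chromatin regulators of neurodevelopmental disorders 11 and 4 (SMARCA2, of both kinds, at 28.2-fold in ESC) and cell cycle genes 12 and 5. Oxidative phosphorylation genes had 14 and 12, mitochondrial ribosome genes 19 and 5, ribosomal protein genes 18 and 5, splicing genes 11 and 5, and proteasome genes 5 and 4. Markers of other cell types had 3 and 3 for blood and endothelium and 4 and 3 for mesenchyme and neural crest. For YY1, 0 of 15 lists passed Fisher's exact test after adjustment, and 0 had an unadjusted p under 0.05. Against matched random lists 0 of the YY1 lists passed after adjustment either. These tests had little power, since ESC-only YY1 regions numbered 242. The most ESC-specific YY1 members in a list was 3, for mitochondrial ribosome genes, beside 26 NSC-specific ones. Neural stem and progenitor genes had 26 NSC-specific and 1 ESC-specific members, and ribosomal protein genes 36 and 2. That no list passed therefore does not show that YY1 lists are alike in the cell types. All 143 list tests, of which 64 passed, were adjusted together, and 55 of the 64 also passed against matched random lists.

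Counted by gene rather than by class, SOX2 regions lay near neural stem and progenitor genes and signalling genes more often than near other genes in both cell types. In NSC, 40 of 53 neural stem and progenitor genes (75.5%) had a SOX2 region within 50 kb, against 36.1% of other genes (odds ratio 5.45, 2.92 to 10.2, adjusted exact p = 6.74e-08). Signalling genes of the Notch, Wnt, Hedgehog and FGF pathways had 41 of 57 (71.9%, adjusted exact p = 3.44e-07) and cell cycle genes 23 of 35 (65.7%, adjusted exact p = 0.00185). Mesendoderm genes were low, at 4 of 28 (14.3%, adjusted exact p = 0.0409). HOX genes had 0 of 39 (adjusted exact p = 2.36e-07, and 0.0734 against matched random lists), and chromatin regulators had 21 of 38 (adjusted exact p = 0.0413, and 0.122 against matched random lists). In ESC, SOX2 regions lay near 26 of 35 pluripotency genes (74.3%, against 24.6% of other genes, odds ratio 8.87, 4.15 to 18.9, adjusted exact p = 9.47e-09), 38 of 57 signalling genes (66.7%, adjusted exact p = 3.31e-10) and 35 of 53 neural stem and progenitor genes (66.0%, adjusted exact p = 2.56e-09). Cell cycle genes had 15 of 35 in ESC (adjusted exact p = 0.0413, and 0.0713 against matched random lists). The other 10 lists in NSC and 12 in ESC did not pass. By adjusted exact p, the mesendoderm call in NSC was lost without NSC SOX2 replicate 2, with stricter peaks (0.136), with the nearest gene (0.116) and against genes with a region (0.210). The cell cycle call in NSC was lost with the nearest gene (0.0814) and against genes with a region (0.0761), and that in ESC without ESC SOX2 replicate 1 (0.128), among others.

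YY1 sat at the ends of genes for core cell functions. In NSC a YY1 region lay within 1 kb of a gene end for 49 of 69 mitochondrial ribosome genes (71.0%), 48 of 72 ribosomal protein genes (66.7%), 40 of 60 oxidative phosphorylation genes (66.7%), 19 of 31 proteasome genes (61.3%), 23 of 39 splicing genes (59.0%), 22 of 38 chromatin regulators (57.9%) and 15 of 35 cell cycle genes (42.9%). Other genes stood at 22.8% to 23%, and the adjusted p ran from 1.01e-15 for the mitochondrial ribosome to 0.0213 for the cell cycle, whose call was lost without NSC YY1 replicate 2, with stricter peaks and against genes with a region. In ESC the same lists but the cell cycle passed, with 34 of 69 mitochondrial ribosome genes (49.3%), 25 of 60 oxidative phosphorylation genes (41.7%), 15 of 39 splicing genes (38.5%), 10 of 31 proteasome genes (32.3%), 11 of 38 chromatin regulators (28.9%) and 19 of 72 ribosomal protein genes (26.4%), against 9.18% to 9.28% of other genes. HOX genes (0 of 39), mesendoderm genes (0 of 28) and mesenchymal genes (0 of 20) had no YY1 region called at their ends in NSC, with adjusted p of 0.000261, 0.00319 and 0.0194, of which the mesenchymal call was lost with a reciprocal overlap of 50% (adjusted exact p = 0.132). Neuronal genes had 3 of 40 (adjusted exact p = 0.0488, and 0.106 against matched random lists). In ESC the signalling list had 0 of 57 (adjusted exact p = 0.0234). For single members the window was 50 kb from either gene end, so the regions named next need not lie at the gene's end. High values of NSC-only YY1 regions were found within 50 kb of MYCN (21.2-fold), PSMD1 (21.4-fold) and the splicing factor gene SRSF1 (20.9-fold). Others were ARID1A, a chromatin remodelling subunit (20.6-fold), and MRPL40 (18.3-fold). MRPS18B, RPS18 and MOG, the highest ESC-specific members of their lists, lie in the chromosome 6 stretch without NSC peaks. The regions counted for MRPS18B and RPS18 are those named above as nearest to PPP1R10 and DAXX.

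**Figure D4:**
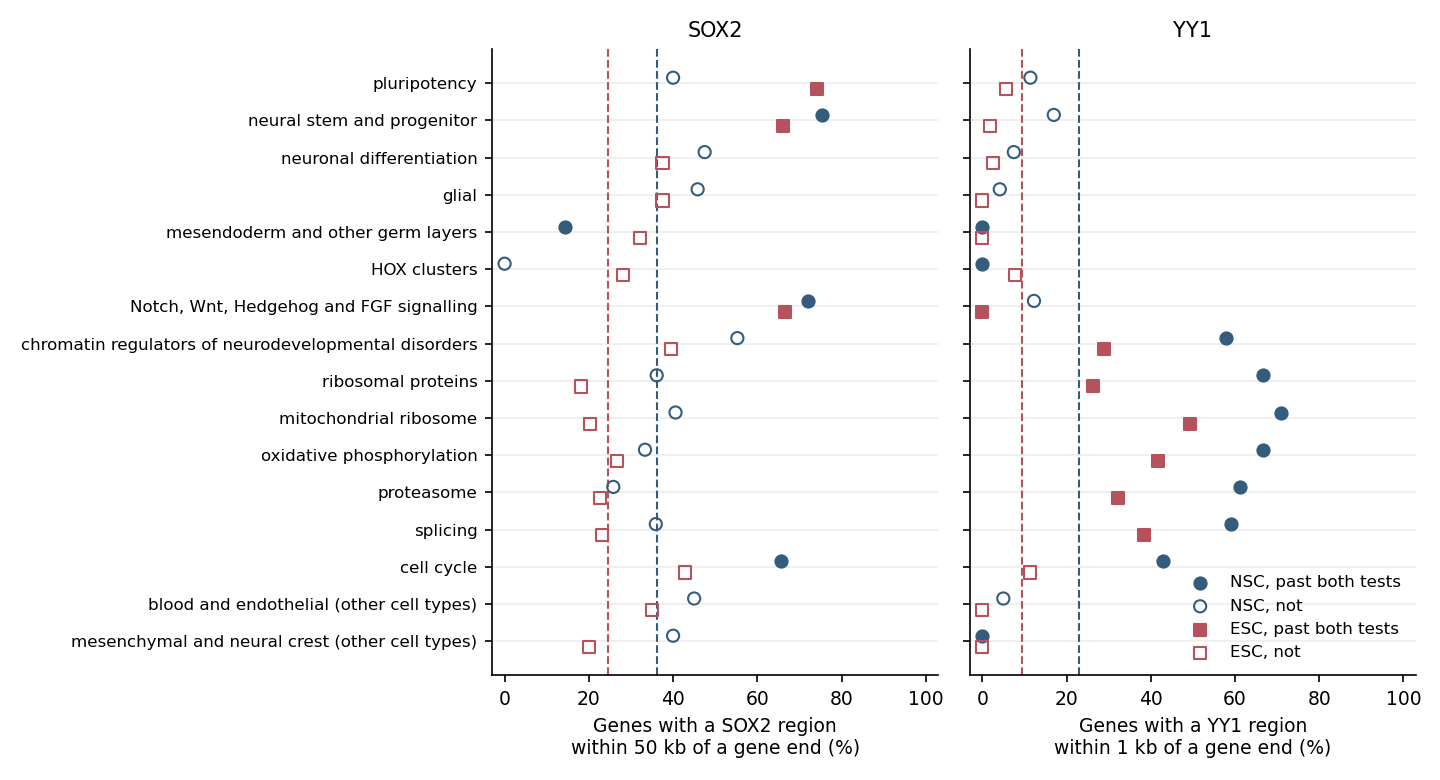
For the 16 gene lists, the x axes give the percentage of list genes with a SOX2 region within 50 kb (left) or a YY1 region within 1 kb (right) of a gene end, in NSC (circles) and ESC (squares); filled symbols passed both Fisher's exact test and the test against matched random lists, and dashed lines mark all protein-coding genes outside a list. YY1 lies at 71.0% of mitochondrial ribosome genes in NSC and 49.3% in ESC.

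NSC H3K27ac and H3K4me1 showed which of these genes lay in marked chromatin. H3K27ac stood within 1 kb of a gene end for 35 of 35 cell cycle genes, 95.8% of ribosomal protein genes, 93.5% of proteasome genes, 92.3% of splicing genes, 91.3% of mitochondrial ribosome genes, 90.0% of oxidative phosphorylation genes and 81.6% of chromatin regulators, against 47.6% to 47.7% of other genes (adjusted p from 6.09e-17 to 0.000118). It was low at HOX genes (0 of 39), blood and endothelial genes (1 of 20), mesendoderm genes (10.7%), glial genes (16.7%), neuronal genes (20%) and pluripotency genes (20%), with adjusted p from 1.45e-10 to 0.00542. Neural stem and progenitor genes stood at 56.6% (adjusted exact p = 0.356). The glial call was lost without NSC H3K27ac replicate 1. H3K4me1 lay within 50 kb of 35 of 35 cell cycle genes, 97.4% of chromatin regulators, 96.7% of oxidative phosphorylation genes, 93.0% of signalling genes and 90.6% of neural stem and progenitor genes, against 73.4% of other genes, and these 5 lists passed both tests. A further 4 lists passed Fisher's exact test for H3K4me1 and not the matched lists, with adjusted p of 0.0666 for ribosomal proteins, 0.0886 for splicing, 0.0622 for mesendoderm and 0.281 for HOX genes. Each of the 5 calls was lost under at least 1 alternative. The neural stem and progenitor call was lost without either H3K4me1 library, those of the chromatin regulators and signalling genes without replicate 1, that of oxidative phosphorylation with stricter peaks and the nearest gene, and that of the cell cycle with a reciprocal overlap of 50%.

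SOX2 and YY1 met at a minority of sites, and far more often than random placement along whole chromosomes would give. In NSC, 1143 of 11557 SOX2 regions (9.89%) overlapped a YY1 region, against a mean of 22.96 over 100 shuffles of position within chromosomes, a ratio of 49.8. In ESC, 84 of 6552 (1.28%) did, against 3.56 shuffled, a ratio of 23.6. The highest shuffle gave 35 in NSC and 10 in ESC (permutation p = 0.0099 in each, the smallest that 100 shuffles can give). Near gene ends 34.8% of NSC and 6.55% of ESC SOX2 regions overlapped YY1, and away from them 7.57% and 0.984%. When shuffles kept gene-end regions at gene ends, the ratios were 17.1 in NSC and 11.9 in ESC, and with a reciprocal overlap of 50% they were 100 and 44.3. No shuffle kept regions within marked chromatin. In NSC, 81.8% of YY1 and 46.6% of SOX2 regions lay on H3K27ac, which covered 21.1 Mb. How much of the ratio comes from both factors lying in such chromatin was not tested.

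Distal H3K4me1 regions were compared by whether they also carried H3K27ac. SOX2 lay in 4139 of 9694 regions with H3K27ac (42.7%) and in 3981 of 36922 without it (10.8%), an odds ratio of 6.17 (5.85 to 6.49, Fisher's exact test on regions). YY1 lay in 6.77% and 0.788% (odds ratio 9.14, 7.94 to 10.5). Regions with H3K27ac were wider, with a median of 1103 bp against 724 bp. Per 100 kb of H3K4me1 sequence there were 32.5 SOX2-bound regions with H3K27ac and 12.6 without, and 5.15 and 0.923 YY1-bound regions. In all, 21.5% of H3K4me1 regions overlapped H3K27ac, and 45.0% of H3K27ac regions overlapped H3K4me1.

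The H3K27ac domains of NSC that covered most sequence lay at genes of several kinds, with SOX2, POU3F3, POU3F2 and NES among the 10 nearest genes. Stitching regions by distance gave 13788 domains with a median of 807 bp covered by H3K27ac. The 10 that covered most were nearest to SKIDA1 (22.4 kb covered, chromosome 10, 21494132 to 21535537), CUEDC1 (19.6 kb), SOX2 (18.9 kb, chromosome 3, 181707626 to 181739984), POU3F3 (18.6 kb), the histone gene H2BC8, NUAK2, POU3F2 (15.8 kb), URM1, the histone gene H2BC3 and NES (13.2 kb). The domain at SOX2 held 9 SOX2 regions and 1 YY1 region, and that at POU3F3, a POU factor of neural progenitors, held 6 and 3. Of the 100 domains that covered most, 97% held a SOX2 region and 66% a YY1 region, against 31.7% and 32.1% of the rest. Broad domains offer more sequence for an overlap, and no test was made.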

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

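The test of the difference in co-occupancy between the cell types and the count of peaks on alternate sequences were chosen after the results were seen.

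SOX2 and YY1 co-occupancy differed between the cell types. The ratio of observed to shuffled overlap was 49.8 in NSC and 23.6 in ESC, so that the NSC ratio was 2.11 times the ESC ratio (exact binomial test on the regions that overlapped, p = 3.04e-13). When shuffled regions kept their distance class to gene ends, the NSC ratio was 1.43 times the ESC ratio (exact binomial test, p = 0.00110). The region counts behind these ratios were 1143 in NSC and 84 in ESC, and the spread between libraries was not part of this test. Neither kind of shuffle kept regions within marked chromatin.

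NSC libraries held 48 peaks on alternate sequences of the reference, a part of the files that the comparisons did not use, and the 4 ESC libraries held 0. Among the 8 NSC libraries the number ran from 0 to 15, and 2 of the 48 lay on alternate copies of chromosome 6.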

How the results depend on the processing

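The replicate block, left-out libraries and other alternatives were planned, except those without gene-rich intervals free of NSC peaks and with matched random lists, which were chosen after seeing the data. Over 96 results and 25 settings, 924 alternative values were computed. Among results that answer a comparison, 134 values stayed, 19 moved, 3 turned direction and 1 lost its call. Tests stayed if they kept their direction and side of the threshold, counts if they kept within a set ratio, and shares if they kept within their spread. Tests of gene-end shares could not pass the threshold with 2 libraries per group, so only their direction could change. Among single lists and named parts, 700 stayed, 62 lost their call, 4 moved and 1 turned. The mean share of YY1 peaks at gene ends, NSC minus ESC, turned to 12.7 percentage points with equal numbers of peaks, and over left-out libraries it ranged from −13.4 to 1.40, with 0.603 without ESC YY1 replicate 1. The odds ratio of H3K27ac at YY1 over SOX2 regions at gene ends ranged from 0.964 to 3.36 over left-out libraries. NSC H3K4me1 regions numbered 24681 with stricter peaks and 30814 with a reciprocal overlap of 50%. The share of ESC SOX2 regions called in NSC was 23.9% with stricter peaks, 12.6% with equal numbers, 19.2% with a reciprocal overlap and 22% to 29.6% over left-out libraries. For ESC YY1 regions these were 85.5%, 77.9%, 53.7% and 66.6% to 88.5%, with 85.6% without gene-rich intervals free of NSC peaks. YY1 lists that differed between the cell types numbered 1 with equal numbers of peaks and 0 to 2 over left-out libraries. Pairing by replicate number gave a sharing odds ratio of 10.6 (exact sign-flip permutation, p = 0.5, the smallest that 2 pairs allow), and gene-end differences of 4.90 for SOX2 and −5.98 for YY1. Fold enrichment at shared regions gave no sign that equal numbers belong together (r = −0.00771 across 1676 SOX2 regions and −0.0215 across 1765 YY1 regions, which are not independent replicates). Leaving out a library leaves 1 in its group, so those values of gene-end shares carry no test. The sharing odds ratio ranged from 4.89 to 24.5, that of H3K27ac at NSC-only over ESC-only SOX2 regions from 15.2 to 34.5, and that of H3K27ac at YY1 over SOX2 regions from 2.09 to 6.97. With a library left out, its group holds all peaks of the other library, without the need for a second call, so regions can rise in number (H3K27ac domains to 15797 and 17679). The cause of these shifts was not tested. The 2 motif alternatives were not run, for lack of a genome sequence. Depth is unknown, so a missing peak cannot be told from a shallow library.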

Other observations

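The tests of SOX2-bound and of enhancer chromatin, of reads lost at alternate copies of the reference and of low NSC chromatin activity were chosen after the results were seen; a first SOX2 test, for both kinds of chromatin and without regard to fold, was set before and replaced after its value was seen, and those for ESC-only YY1 regions were picked from 9 versions with known values. The other tests were set before theirs.

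NSC YY1 replicate 2 held 13349 of 19488 peaks, or 68.5%, that replicate 1 did not. Of these 41.0% lay within 1 kb of a gene end, and their median fold enrichment was 5.57 against 15.4 for the peaks called in both. Within 10 equal bins of fold enrichment, distal peaks called in replicate 2 alone overlapped NSC SOX2 regions less often than those called in both. The odds ratio was 0.605 (0.533 to 0.688), and 0.682 without regard to fold, with shares of 27.3% and 35.6%. The higher overlap predicted for SOX2-bound chromatin as the source was thus not seen. The test compares YY1 peaks only with other YY1 peaks, so it cannot exclude such chromatin as a source of part of the extra peaks. For enhancer chromatin the odds ratios within bins were 0.748 (0.660 to 0.847) for NSC H3K4me1 and 0.445 (0.393 to 0.504) for NSC H3K27ac. Without regard to fold that of H3K4me1 was 1.09 (0.992 to 1.21) and that of H3K27ac 0.389. Distal peaks in replicate 2 alone overlapped H3K4me1 at 38.2% and H3K27ac at 43.2%, against 36.1% and 66.2% of those called in both. Over all peaks, H3K4me1 overlap was 21.8% in replicate 2 and 13.2% in replicate 1. The test within bins therefore does not decide on enhancer chromatin as a source. Of the 4878 replicate 2 peaks with the highest fold enrichment, 4219 or 86.5% were called in replicate 1, against 5.58% of an equal share of peaks with the lowest, so weaker sites that pass the threshold in 1 library may account for most of the difference.

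Most ESC SOX2 regions were not called in NSC. If these were regions near the calling threshold, strong ESC regions would be called in NSC, but 633 of the 1641 with the highest fold enrichment, or 38.6% (36.2 to 41.0), had a peak in an NSC SOX2 library, against 30.9% of the 1638 with the lowest. Loss of NSC reads at alternate copies of the reference was looked for in gene-rich intervals free of NSC peaks. These held 2.72% (120 of 4404) of the ESC-only SOX2 regions, so loss within them leaves most unexplained. Loss in shorter or gene-poor stretches does not enter this share and was not tested. NSC SOX2 libraries held 16218 and 17060 peaks, against 9931 and 8402 in ESC. NSC H3K27ac, from separate libraries, lay at 2.38% of ESC-only SOX2 regions and at 55.7% of shared ones. Both argue against lower NSC depth as the source of most uncalled regions, although depth itself is unknown. A difference in SOX2 binding between the cell types stays open as a hypothesis that these lists cannot test further.

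Some ESC-only YY1 regions, 45 of 242, lay in intervals chosen for holding no NSC peak, which makes every YY1 region there ESC-only. Of all ESC YY1 regions 2.12% lay there, against 6.50% of the genes and 4.71% of the sequence. Part of that sequence is in long stretches with few or no ESC peaks, so its share is no expectation for YY1. Loss of NSC reads where the reference holds alternate copies is a candidate explanation that no table can locate: genes of 6 lists with core cell functions made up 4 of 415 genes in the 11 intervals with ESC-only YY1 regions (odds ratio 0.621, 0.230 to 1.67), a spread that includes 1. Low activity of these genes in NSC cannot be told apart from it at this size, since among genes with ESC YY1 and without NSC H3K27ac the core lists held 2 of 37 inside the intervals and 3 of 118 elsewhere (odds ratio 2.19, 0.352 to 13.6). Versions that were not chosen decide no more: over all 60 intervals the first odds ratio was 0.188 (0.0700 to 0.505), for intervals that mostly hold no ESC-only YY1 region, and without the ESC YY1 condition the second was 1.76 (0.588 to 5.28) over all 60 and 6.09 (2.03 to 18.3) over the 11, an excess that picking intervals by ESC YY1 favours. In the chromosome 6 stretch, where POU5F1 lies, the second was 6.48 (0.996 to 42.1, 2 of 16 genes) and 6.74 (1.55 to 29.3) without that condition, which lean against low activity there but rest on 2 core genes in a stretch noticed for its ESC-only YY1 regions, so the source of the missing NSC peaks stays open.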
